A study of Mus musculus with 6 samples.

How the data were processed

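Messenger RNA from the liver of mice of the C57BL/6J strain was sequenced in 6 samples, 3 titled as wild type (WT) and 3 as knockout of Cry1 (CRY1 KO). The labels give liver as the tissue and hepatocyte as the cell type, and no sorting of cells. They describe phenol-chloroform extraction and a stranded Illumina library kit for polyadenylated RNA. They give no time of day, sex, age or feeding state, and nothing in them says that the replicates were separate animals, so the p-values measure the spread between these samples, which may be in part technical. Groups and replicate numbers were taken from the sample titles. Every title also carries the prefix NC, whose meaning the labels do not give. It may name a condition shared by all samples, and it was not interpreted here.

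The deposited table holds 1 value per gene and sample for 15092 genes, and all 6 of its columns were matched to samples by title. The values were deposited as whole numbers and were taken here as estimated counts. This was inferred from the low values described below and from StringTie being named, and which step made the values is not known. Per the submitters' processing notes, the tools were Trim Galore 0.6.7, HISAT2 2.2.1, StringTie 2.1.7 and limma 3.42.2, and the genome build was GRCm39 (mm39). The notes used here give no order or settings for these tools, and the annotation and the use of strand are not given in the sources used here. In every library more genes had the value 3 than 1, 2 or 4 (125 against 22, 56 and 70 in WT 1), so a single unit of the table is not a single fragment, and low values carry less information than they would as raw counts. The smallest sum of a gene over the 6 libraries was 11, so genes with lower sums were not analysed here. Values of genes from families of near-identical copies, such as the major urinary proteins, the Cyp3a genes, the tubulins and the H2-Q genes, depend on how the authors' tools assigned shared reads and are uncertain for that reason.

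Library totals ranged from 79708703 to 91316332. Genes were kept with edgeR 4.0.16 (filterByExpr, minimum count 10, minimum total 15), which left 13816 genes for testing and removed 1276. Libraries were scaled by the trimmed mean of M values (TMM), and groups were compared with edgeR's quasi-likelihood test with robust estimation and Benjamini-Hochberg adjustment over all tested genes, at a threshold of 0.05. Levels are CPM, counts relative to the TMM-scaled library size, as mean ± SD, and fold changes are log2 values of the libraries labelled CRY1 KO minus WT with their standard error (SE). The coefficient of biological variation was 0.211. For Cry1 an exact permutation test of the group means was added.

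Before the data were examined, 52 gene lists with 1014 entries were written from textbook knowledge of the clock, liver metabolism, hormone responses, immunity, stress, growth, zonation and cell types. Of these entries 958 matched the table, 12 of them through another symbol. The 48 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. Camera compares a list with all other genes, while fry asks whether the list moves on balance in a direction. The rule for naming genes was also set before the data were examined. It takes Cry1 and the core clock genes, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, up to 4 members with the smallest p in each list that passed camera or had at least 2 called members, and called genes near Cry1. Not every gene that the rule takes is reported here. Some genes that passed only when adjusted over a list alone, among them those moving against the direction of their list, were named outside the rule after their values were seen. Called genes near Cry1 were counted in a list of 30 neighbours and compared with other genes by Fisher's exact test. The reference at hand was of another build, so gene order alone was used from it, and no coordinates are given.

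The procedure was tested on simulated counts drawn from the means, library sizes and dispersions of this comparison, with 13610 genes in the fit. Changes of 1.5-fold, 2-fold and 4-fold were planted in 67, 67 and 66 genes, leaving out genes with low mean counts. The procedure recovered 14.9% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 89.4% of those changed 4-fold, and 9 of its 122 calls were not planted. DESeq2 made 165 calls on the same simulated data, of which 35 were not planted. In a simulation with 13621 genes, camera called 1 of 40 unchanged lists and 10 of 10 lists changed 1.5-fold. The simulated genes were drawn independently of each other. In the data genes of a list move together, with an estimated correlation of 0.59 for Kupffer markers. The simulation therefore does not give the rate of false list calls here. The alternatives tried were the replicate number as a block, DESeq2 1.42.0, limma voom, the size factors of DESeq2 in edgeR, no scaling, no filter, a filter at a mean count of 50, a test against a 1.5-fold change, and leaving out each library. Chosen after seeing the data were a newer form of the edgeR deviance, library sizes without major urinary protein and mitochondrial genes, and the nearest 10, 25 or 50 tested genes on each side of Cry1. R was version 4.3.3, and plots were drawn with matplotlib 3.10.9.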

Results

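Liver RNA was compared between 3 libraries of wild-type mice and 3 libraries labelled CRY1 KO. Cry1 encodes a cryptochrome, a repressor of the CLOCK and BMAL1 transcription factors in the circadian clock. The total estimated count was 91316332, 83941470 and 88541861 in WT 1, 2 and 3 and 81969920, 87480152 and 79708703 in CRY1 KO 1, 2 and 3. Genes of the major urinary proteins took between 7.52% and 19.0% of the counts of a library, and mitochondrially encoded genes between 5.82% and 9.45%.

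Cry1 was not measurably lower in the libraries labelled CRY1 KO. Its estimated counts were 413, 579 and 694 in the WT libraries and 561, 521 and 445 in the libraries labelled CRY1 KO. The level was 6.31 ± 1.32 CPM in WT and 6.19 ± 0.88 CPM in CRY1 KO (SD, n = 3 each), a log2 difference of -0.03 (SE 0.19, edgeR adjusted p = 0.954). The 95% interval of the log2 difference, taken from limma on log2 CPM and not from edgeR, ran from -0.45 to 0.42. The exact two-sided permutation p was 1, where the smallest p that 3 against 3 libraries allow is 0.1. The value covers the whole gene, so it cannot show whether particular exons are missing, and the knockout labels are not checked by it. Each direction given here is that of libraries labelled CRY1 KO against WT, with this limit.

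Pearson correlations of log2 CPM lay between 0.979 and 0.983 within the libraries labelled CRY1 KO, between 0.969 and 0.978 within WT, and between 0.965 and 0.975 across the groups. The first principal component, with 34.2% of the variance, separated the groups. The second, with 22.6%, set WT 1 at 48.80 apart from the other libraries, which lay between -32.40 and 4.81. Haemoglobin genes took 0.267% of the counts in WT 1 and between 0.0435% and 0.0917% in the other 5 libraries. Lpin1, a phosphatidate phosphatase, stood at 417.9 CPM in WT 1, at 27.9 and 22.6 CPM in WT 2 and WT 3, and between 320.2 and 774.9 CPM in the libraries labelled CRY1 KO. Hmgcs1, an enzyme of cholesterol synthesis, stood at 777.5 CPM in WT 1 and between 120.7 and 195.1 CPM in the others.

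The 10 largest rises among called genes included the cell cycle kinase gene Wee1 (log2 3.07, SE 0.30), the clock genes Per3 (2.07, SE 0.13) and Per2 (4.01-fold, SE 0.21 on the log2 scale), and Klf10 (2.63, SE 0.40), which encodes a Krüppel-like transcription factor. Phf11c rose 4.60-fold. On the log2 scale Sbk1 rose by 1.69, Lingo4 by 1.58 and Slc25a47, a mitochondrial carrier gene of the liver, by 1.56. The drug-metabolising P450 gene Cyp3a11 rose from 2247 ± 247 to 7029 ± 1085 CPM (SD, n = 3 each; log2 1.64, SE 0.15, edgeR adjusted p = 0.00379), and its relative Cyp3a44 rose by 1.69. Among falls, Ikzf4 had a log2 change of -3.05 (SE 0.54), Cables1 -2.51 (SE 0.19), Jchain, which encodes the joining chain of secreted antibodies, -2.45 (SE 0.33), Mmd2 -2.24, Slc37a1 -2.19 and Exoc3l4 -1.78. The β-tubulin genes Tubb2a (-1.77) and Tubb2b (-1.69), the amino acid transporter gene Slc1a4 (-1.70) and Tmem51 (-1.67) also fell.

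In all, 235 of 13816 genes passed the edgeR test, 146 higher and 89 lower in the libraries labelled CRY1 KO, and 2860 genes had an unadjusted p under 0.05. Of the called genes 40 were at least 2-fold higher and 34 at least 2-fold lower, and in each of the 235 the groups did not overlap. Among tested genes 27.3% had groups that did not overlap, where chance gives 10% on average over splits. Genes move together, so the share in a single split can lie far from that average, and the excess was not tested. The count varied with the library left out: it was 565 without WT 1, 17 without WT 2, 844 without WT 3, and 40, 20 and 30 without CRY1 KO 1, 2 and 3. Genes with an unadjusted p under 0.05 then ran from 1942 without CRY1 KO 3 to 3683 without WT 3. These fits also had fewer libraries, so a loss of power and an effect of the library left out cannot be told apart. DESeq2 called 1284 genes, and 18 passed a test against a 1.5-fold change.

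All 16 tested clock genes whose promoters carry E-boxes or D-boxes were higher in every library labelled CRY1 KO than in every WT library, with a median log2 difference of 1.70. Of these 8 rose past the threshold over all genes and 16 when adjusted over the list alone. Among them, Per3 rose from 5.10 ± 0.60 to 21.4 ± 1.73 CPM (SD, n = 3 each; edgeR adjusted p = 0.00125), and Tef (log2 1.53), Wee1 (3.07), Per2 (4.01-fold), Hlf (1.16), Nr1d2 (0.86) and Cry2 (0.86) rose too. Ciart (4.05), Usp2 (3.66), Per1 (2.74), Dbp (2.12), Bhlhe40 (1.87), Bhlhe41 (1.35), Nr1d1 (0.54) and Tspan4 (0.50) did not pass over all genes. Per1 varied between WT libraries, at 19.4, 2.53 and 5.23 CPM.

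**Figure D1:**
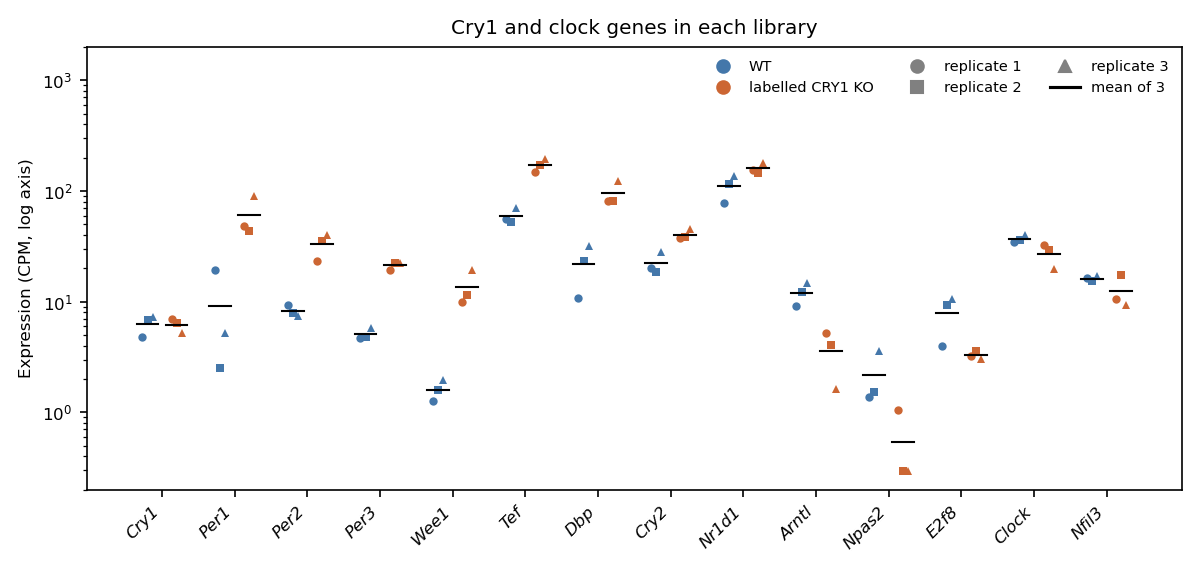
Expression of Cry1 and 13 clock genes in CPM (log axis) in each of the 6 libraries, with symbols for the replicate number and black bars for the mean of 3. Cry1 lies at means of 6.31 CPM in WT and 6.19 CPM in CRY1 KO, while Per3 lies at means of 5.10 and 21.4 CPM.

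The 5 clock genes repressed through ROR elements had negative log2 differences, with 0 past the edgeR threshold over all genes and 4 lower when adjusted over the list alone. Arntl, which encodes BMAL1, stood at 12.02 ± 2.76 CPM in WT and 3.61 ± 1.83 CPM in CRY1 KO (SD, n = 3 each; log2 -1.73). Npas2 had a log2 difference of -2.00, E2f8 of -1.28, Clock of -0.44 and Nfil3 of -0.38. In 20 of these 21 E-box, D-box and ROR-element genes the groups did not overlap, Nfil3 being the exception. The clock family joins these lists with those of other clock components, rhythmic liver outputs and proteins reported to bind cryptochromes. By DESeq2, 30 of its 67 tested genes passed, against 14 in the edgeR test, 13 higher and 1 lower (Avpr1a, -1.05). Of the 14, 8 were E-box or D-box genes, 4 were liver outputs and 2 were proteins reported to bind cryptochromes.

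By camera the E-box and D-box list was higher (adjusted p = 8.98e-15; adjusted p = 0.577 with an estimated correlation) and the ROR-element list lower (adjusted p = 0.00664; adjusted p = 0.577 with an estimated correlation). The adjustment gives the same value of 0.577 to lists whose unadjusted p differ, here and below. With an estimated correlation the unadjusted camera p was 0.0163 for the E-box and D-box list and 0.121 for the ROR-element list. For the histone list below, with the same adjusted p, it was 0.277. By fry the E-box and D-box list passed (adjusted p = 0.0201) and the ROR-element list did not (adjusted p = 0.130). The count of called clock family genes was 26 without WT 1, 2 without WT 2, and 8, 3 and 6 without CRY1 KO 1, 2 and 3, and the ROR-element list lost its call without WT 3 (adjusted p = 0.051).

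Rhythmic outputs of the clock in liver included called rises of Elovl5 (0.94), a fatty acid elongase gene, Gys2 (0.91), which encodes liver glycogen synthase, and Por (0.82), the electron donor of P450 enzymes, and the fall of the vasopressin receptor gene Avpr1a. Of the 23 tested members, 3 rose, 1 fell and 19 did not pass, with 6 higher and 1 lower when adjusted over the list alone, and the list was higher by camera (adjusted p = 0.00814; adjusted p = 0.577 with an estimated correlation). In the list of detoxification genes under the PAR bZIP factors, the carboxylesterase genes Ces2a (0.52) and Ces2e (0.53) and Por rose, 8 of 11 members did not pass, and 5 were higher and 1 lower (Ces3b, -0.38) when adjusted over the list alone. The nuclear receptor gene Nr1i3 had a difference of 1.33 and was not called. This list was higher by camera (adjusted p = 0.00664; adjusted p = 0.577 with an estimated correlation) and passed fry (adjusted p = 0.0415). Of 11 nuclear receptors and other proteins reported to bind cryptochromes, Foxo1 (0.98) and Hnf4a (0.73) rose, 4 were higher when adjusted over the list alone, and the camera adjusted p was 0.0273 (adjusted p = 0.577 with an estimated correlation). Without WT 3 the camera adjusted p was 0.0529 for outputs and 0.051 for detoxification, and that of the last list was 0.0556, 0.0821 and 0.0587 without WT 2, CRY1 KO 2 and CRY1 KO 3. The median of the outputs list moved from 0.53 to 0.91 without WT 1, and that of the cryptochrome partners from 0.17 to 0.07, 0.28 and 0.10 without WT 2, CRY1 KO 1 and CRY1 KO 3.

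Scd1, the stearoyl-CoA desaturase gene of fatty acid synthesis, rose from 3174 ± 566 to 7533 ± 1163 CPM (SD, n = 3 each; log2 1.25, SE 0.17, edgeR adjusted p = 0.019), and Elovl5 and Me1 (0.67), the malic enzyme gene, rose with it. In that list of 22 genes 19 did not pass, and 5 were higher and 1 lower (Agpat2, -0.53) when adjusted over the list alone. Pklr (0.74), which encodes liver pyruvate kinase, and Gys2 rose among 21 genes of glycolysis and glycogen, with 6 higher when adjusted over the list alone, and Slc2a2 (0.53) and Txnip (2.25) did not pass over all genes. Cpt1a (0.71), which encodes the carnitine palmitoyltransferase that admits fatty acids to mitochondria, rose among 30 tested genes of fatty acid oxidation and PPARα targets, and Foxo1 rose among 16 genes of gluconeogenesis, each list with 1 gene when adjusted over the list alone. Of 22 glucocorticoid receptor targets 0 passed the edgeR test over all genes and 1 when adjusted over the list alone. In that list Zbtb16 had a difference of 3.29 and Fkbp5 of 1.56. Of 22 genes higher in female than male liver Cyp3a44, Fmo2 (1.14) and Trim24 (0.72) rose, and when adjusted over the list alone 3 were higher and 2 lower, Cyp2c69 (-0.91) and Cyp2c40 (-1.08).

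These lists were higher by camera, with adjusted p = 0.0147 for fatty acid synthesis, 0.00831 for glycolysis and glycogen, 0.00577 for fatty acid oxidation, 0.0128 for gluconeogenesis, 0.00532 for glucocorticoid targets and 0.0188 for female-biased genes (adjusted p = 0.577 with an estimated correlation for each). Without WT 3 the adjusted p of these lists other than fatty acid oxidation became 0.106, 0.051, 0.174, 0.051 and 0.156, and that of female-biased genes was 0.0587 without CRY1 KO 3. On glucocorticoid targets WT 1 had a median log2 deviation of 0.37, within the 0.08 to 0.47 of the libraries labelled CRY1 KO, while WT 2 and WT 3 lay at -0.63 and -0.85. WT 1 also lay within their range on fatty acid synthesis (0.129, against 0.121 to 0.354) and gluconeogenesis (0.141, against 0.135 to 0.182). On fatty acid oxidation WT 3 did (0.070, against 0.012 to 0.217). On glycolysis and glycogen and on female-biased genes the medians of the groups did not overlap. Without WT 1 the list median moved from 0.35 to 0.80 for glucocorticoid targets, from 0.35 to 0.74 for fatty acid synthesis, from 0.19 to 0.39 for gluconeogenesis, from 0.18 to 0.28 for glycolysis and glycogen and from 0.37 to 0.23 for fatty acid oxidation. Without CRY1 KO 3 that of fatty acid oxidation was 0.21, and that of female-biased genes fell from 0.66 to 0.37, and without WT 3 to 0.32, while that of fatty acid synthesis became 0.19. The companion list of 28 genes higher in male than female liver had 0 called genes and a median of 0.05. It did not pass camera (adjusted p = 0.282).

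**Figure D2:**
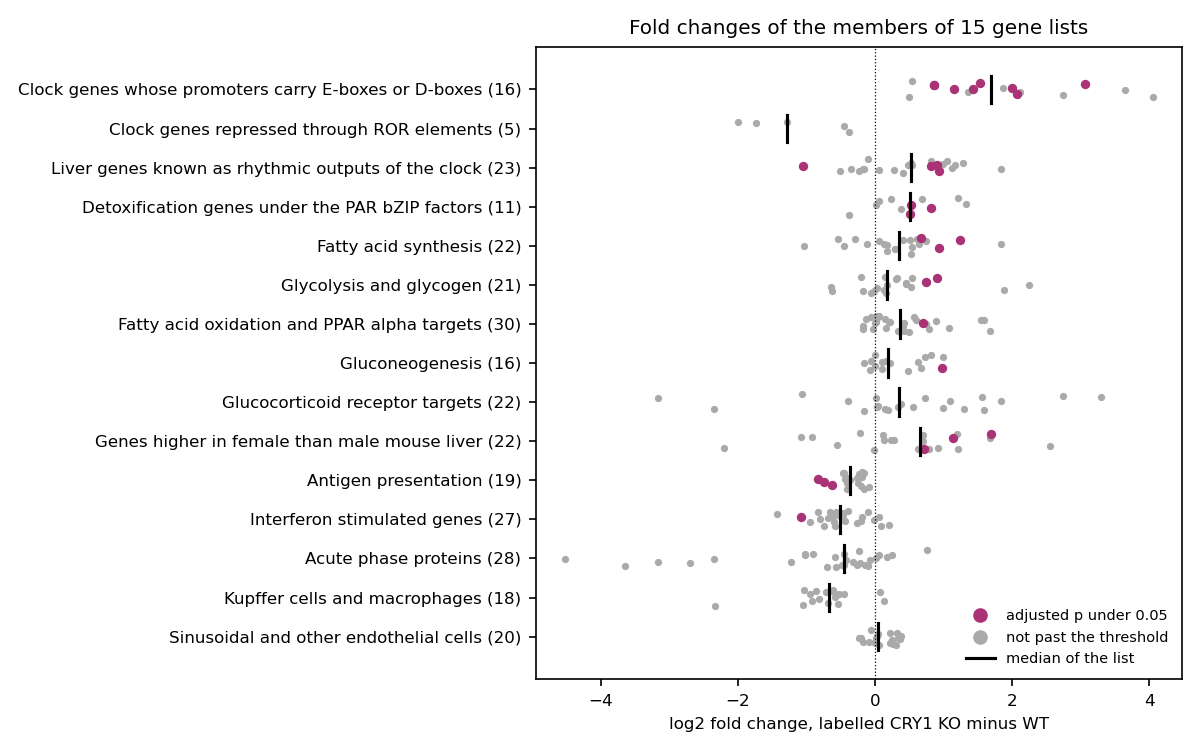
Log2 fold change (labelled CRY1 KO minus WT) of each tested member of 15 gene lists, with the number of members in parentheses, called genes in purple, other genes in grey and the list median as a black bar. The E-box and D-box genes lie to the right of 0 with a median of 1.70, and the antigen presentation genes to the left with a median of -0.36.

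Of 19 tested antigen presentation genes 3 fell. They were H2-Q6 (-0.83) and H2-Q7 (-0.63), class I genes of the major histocompatibility complex with near-identical copies, and Nlrc5 (-0.74), which encodes a class I transactivator. These calls were lost with the replicate number as a block. The list was lower by camera (adjusted p = 5.67e-05; adjusted p = 0.577 with an estimated correlation). All 19 members had negative differences, 16 of them short of the threshold, and 7 were lower when adjusted over the list alone. The interferon-induced GTPase gene Ifi47 fell (-1.08) among 27 interferon-stimulated genes, of which 24 had negative differences and 1 passed when adjusted over the list alone. Of 28 acute phase genes 0 passed the edgeR test over all genes. When adjusted over the list alone 2 were lower, Itih3 (-0.57) and Socs3 (-1.02), and 1 was higher, the interleukin-1 receptor gene Il1r1 (0.76), while Hp (haptoglobin, -0.91) did not pass. Of 18 markers of Kupffer cells, the macrophages of the liver, 0 passed, also when adjusted over the list alone. C1qb had a difference of -1.03, C1qa of -0.92, C1qc of -0.95 and Vsig4 of -0.71. Jchain fell among 7 tested markers of B and plasma cells, where 1 passed when adjusted over the list alone, and S100a9 (-1.95) did not pass among 6 neutrophil markers, of which 2 passed when adjusted over the list alone.

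By camera the other lists of this group were lower too, with adjusted p = 0.00532 for interferon-stimulated genes, 0.00664 for acute phase genes, 0.00274 for Kupffer cells, 0.0188 for B cells and 0.0147 for neutrophils. With an estimated correlation they were not called (adjusted p = 0.652, 0.652, 0.579, 0.577 and 0.577 with an estimated correlation, in that order). Kupffer markers had a median log2 deviation of 0.92 in WT 1, 0.31 in WT 2 and -0.28 in WT 3, against -0.35, -0.36 and -0.26 in CRY1 KO 1, 2 and 3. Markers of red blood cells and platelets had 1.74 in WT 1 and between -0.70 and 0.11 in the other libraries. Without WT 1 the adjusted p was 0.104 for interferon-stimulated genes, 0.0767 for acute phase genes and 0.0572 for neutrophils, and without WT 3 it was 0.137 for B cells. Medians without WT 1 were -0.35 in place of -0.67 for Kupffer cells, -0.33 in place of -0.51 for interferon-stimulated genes, -0.25 in place of -0.45 for acute phase genes and -0.96 in place of -1.48 for neutrophils. That of antigen presentation was -0.23 without WT 2, and those of B cells and neutrophils were -0.58 and -2.40 without WT 3.

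**Figure D3:**
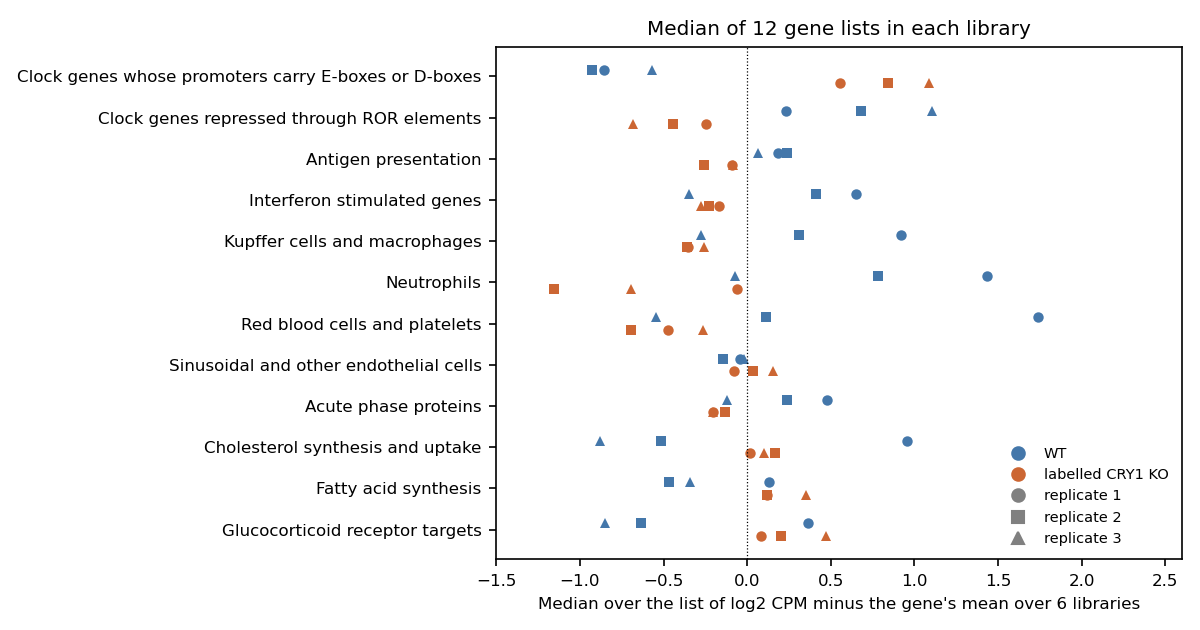
Median over each of 12 gene lists of log2 CPM minus the mean of the gene over the 6 libraries, per library, with WT in blue, libraries labelled CRY1 KO in orange and symbols for the replicate number. WT 1 has the highest Kupffer median at 0.92, and WT 3, at -0.28, lies among the libraries labelled CRY1 KO.

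The other tested cell types did not pass camera with all libraries. Markers of sinusoidal and other endothelial cells had a median of 0.05, hepatocytes -0.04, stellate cells -0.13, bile duct cells -0.02, T and NK cells -0.40, red blood cells and platelets -1.25 and liver capsule 0.14. Some of these lists passed under other settings at the preset correlation. An estimated correlation was run with all libraries only, and 0 lists passed with it. That of T and NK cells was lower without scaling (adjusted p = 0.0498) and without WT 1 (0.0489), CRY1 KO 1 (0.0165) or CRY1 KO 3 (0.0208), while its median was -0.16 without CRY1 KO 2 (0.168). Stellate markers were lower without WT 2 (median -0.33, adjusted p = 0.00295), and endothelial markers were higher without CRY1 KO 1 (0.0495), their median lying between -0.019 and 0.14 over the libraries left out. Red blood cell and platelet markers were lower without WT 3 (0.00847), and their median was -0.18 without WT 1.

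Of 13 mitochondrially encoded genes, all with positive differences such as mt-Co1 (0.49) and mt-Nd2 (0.59), 0 passed the edgeR test over all genes and 4 when adjusted over the list alone. The list was higher by camera (adjusted p = 0.00664; adjusted p = 0.588 with an estimated correlation). Of 39 genes of cytosolic ribosomal proteins 33 had negative differences and 0 passed over all genes or when adjusted over the list alone, with Rps29 at -0.62, Rplp2 at -0.34 and Rps9 at 0.38, and the list was lower by camera (adjusted p = 0.0108; adjusted p = 0.77 with an estimated correlation). The histone gene H1f2 fell (-0.91) among 9 tested replication-dependent histone genes, whose messengers lack a poly(A) tail and are poorly measured in such libraries. With 1 past the threshold when adjusted over the list alone, that list was lower by camera (adjusted p = 0.00831; adjusted p = 0.577 with an estimated correlation). Slc1a4 fell among 20 pericentral hepatocyte genes, with 4 lower when adjusted over the list alone, Lgr5 at -0.78 and Glul at -0.31, and the list was lower by camera (adjusted p = 0.024; adjusted p = 0.577 with an estimated correlation). In the unfolded protein and integrated stress response list, which did not pass camera, the transcription factor gene Atf4 fell (-0.54) and Sesn2 rose (0.86), and of 26 genes 3 were higher and 1 lower when adjusted over the list alone. Among drug-metabolising P450 genes, which also did not pass camera, Cyp3a11 and Cyp3a44 rose, 25 of 27 did not pass, and 4 were higher and 5 lower when adjusted over the list alone, the lower ones being Cyp2c69, Cyp2c67 (-0.63), Cyp2c40, Cyp2c68 (-0.58) and Cyp1a2 (-0.26).

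Calls were lost without WT 1 for ribosomal proteins (adjusted p = 0.342), without WT 3 for pericentral genes (0.147), without CRY1 KO 2 for mitochondrial genes (0.0996), and without CRY1 KO 3 for ribosomal proteins (0.119), histones (0.0699) and pericentral genes (0.0587). The median of the mitochondrial genes moved from 0.31 to 0.13 without WT 1, 0.47 without WT 3 and 0.15 without CRY1 KO 2, and that of ribosomal proteins from -0.12 to -0.06 without WT 1 and -0.07 without CRY1 KO 3. Over all tested lists 21 of 48 passed camera, 11 higher and 10 lower, 12 without WT 3, and 0 with an estimated correlation, while 2 passed fry.

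A targeted allele can carry flanking DNA of another strain, so calls near Cry1 were counted. Tdg, which encodes a DNA glycosylase, fell from 11.6 ± 1.52 to 4.53 ± 0.25 CPM (SD, n = 3 each; log2 -1.36, SE 0.14, edgeR adjusted p = 0.00662), Mterf2 fell by 1.22 and Nfyb, a subunit gene of the NF-Y factor, by 0.75 on the log2 scale. These were 3 of 27 tested neighbours, against 232 of 13788 other genes (odds ratio 7.30, 95% interval 1.40 to 24.3, Fisher's exact two-sided p = 0.0105). When adjusted over the list alone 3 were lower and 2 higher, Nt5dc3 (0.43) and Timp3 (0.61). With the nearest 10, 25 or 50 tested genes on each side, sets chosen after seeing the data, the exact p was 0.291, 0.0531 and 0.091. The exact p was also above 0.05 with the replicate number as a block (odds ratio 5.66, exact p = 0.168) and without scaling (4.70, exact p = 0.199). In these settings 94 and 113 genes were called over all genes, in place of 235. The exact p stayed under 0.05 by DESeq2, with a smaller odds ratio of 2.63 (exact p = 0.0453), and past 1.5-fold with 31.1 (exact p = 0.0346). Over all genes only 18 were called past 1.5-fold and 17 without WT 2, so the large ratios there rest on few genes. The exact p was 0.0937 without WT 1, 0.221 without WT 3, and 0.0742, 1 and 0.0563 without CRY1 KO 1, 2 and 3, and the odds ratio was 33.6 without WT 2.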

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

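Each of the 235 called genes had the same sign in all alternatives run. This was close to fixed in advance, since their groups did not overlap and all alternatives used the same libraries. The median of the E-box and D-box list stayed between 1.55 and 1.85. Deviations of same-numbered libraries correlated at -0.07, -0.01 and 0.07. These values gave no sign that the replicate numbers pair the samples, but so few correlations cannot exclude it. With the replicate block 94 genes passed (55 higher, 39 lower), and the odds ratio near Cry1 was 5.66. DESeq2 called 1284 genes (735 higher, 549 lower) and 30 clock family genes, and 1881 genes had no adjusted p. Without scaling 113 passed (59 higher, 54 lower), with an odds ratio of 4.70. Past 1.5-fold there were 18 (13 higher, 5 lower) and 5 clock family genes. Leaving out a library gave 17 to 844 genes (12 to 477 higher, 4 to 367 lower). It gave 2 to 26 clock family genes and 12 to 24 lists. The Cry1 log2 difference then ran from -0.19 to 0.088 and the odds ratio near Cry1 from 0 to 33.6. Of 49 named genes called, 30 kept their call with the replicate block, 31 without scaling, 44 with limma voom, 14 past 1.5-fold, 47, 10 and 47 without WT 1, 2 and 3, and 17, 11 and 15 without CRY1 KO 1, 2 and 3. H2-Q6, H2-Q7, Nlrc5, Ces2a and Ces2e were among those lost with the replicate block. With an estimated correlation 0 lists passed, the E-box and D-box list having its median of 1.70 and adjusted p = 0.577, and 2 passed fry. The nearest 10, 25 and 50 genes, chosen after seeing the data, gave odds ratios of 3.05, 3.72 and 2.43. Lists that had not passed changed direction in camera: the stress response list with limma voom (median -0.091) and, over libraries left out, between -0.18 and 0.098, and hepatocyte markers without scaling (-0.061) and between -0.087 and 0.013, bile duct markers between -0.19 and 0.12, stellate markers between -0.33 and -0.081 and capsule markers between -0.28 and 0.40. The cause was not tested. Under the stricter filter female-biased genes (median 0.46 in place of 0.66) and histones (-0.21 in place of -0.91) lost their calls (adjusted p = 0.065 each), and the B cell and neutrophil lists had too few members to be tested, by its construction with fewer genes. The prior count of 2 for log2 CPM was not varied, and windows of distance were not run because no annotation of the build was at hand. In the simulation 14.9% of genes changed 1.5-fold were recovered, so many small changes can be missed with 3 libraries per group. The share recovered depends on how many genes change, so it need not hold for these data.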

Other observations

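Tests in this part were chosen after the result was seen, except the search for shared Cry1 sequence and the splits of the samples, which were set before their results were seen. Of 12 tested α- and β-tubulin genes 11 had negative differences and 6 fell by edgeR, Tubb2a, Tubb2b, Tuba4a (-0.82), Tuba1c (-1.10), Tuba1a (-0.80) and Tuba1b (-0.63), a family picked after its values were seen. The camera adjusted p over 10 such families was 3.22e-06 (adjusted p = 0.295 with an estimated correlation), and the median of -0.62 stayed negative in all alternatives run, with 3 called genes with the replicate block, 1 without WT 2 and 2 without CRY1 KO 2. The actin gene Actb fell too (-0.67). All 8 tested Cyp3a genes had positive differences, Cyp3a11 and Cyp3a44 being called, with a median of 1.16 (camera adjusted p over the 10 families 2.06e-05, adjusted p = 0.293 with an estimated correlation) that was positive in all alternatives run. These genes are similar in sequence, so reads shared between them are an open source of joint movement that was not tested.

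The acute phase genes Saa1 and Saa2 stood at 988.6 and 463.4 CPM in WT 1, 127.8 and 29.4 CPM in WT 2 and 13.7 and 3.92 CPM in WT 3, while Saa1 lay between 23.7 and 42.0 CPM in the libraries labelled CRY1 KO. Pck1, the gluconeogenic enzyme gene, stood at 2633 CPM in WT 1, 1024 and 1006 CPM in WT 2 and WT 3, and 2789 to 3418 CPM in the libraries labelled CRY1 KO.

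Other splits of the 6 libraries into 3 and 3 gave at most 3 called genes and 0 called clock family genes. They gave at most 19 lists past camera. The real split gave 235, 14 and 21. In each case 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.

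Cry1 was not measurably lower in the libraries labelled CRY1 KO. In 16 of 16 E-box and D-box genes all CRY1 KO libraries lay above all WT libraries. This argues against an exchange of a WT and a CRY1 KO library after sampling. A genotype wrongly given to an animal or to a whole group is not tested by it. Different sampling times could also separate these genes. Reads that match another annotated transcript exactly are argued against too. Of the 50-base words of the annotated Cry1 transcripts 0% occurred in transcripts of another gene. Inexact matches and sequence outside annotated transcripts were not searched, so reads from these stay open. A targeted allele that still gives transcript may account for the log2 difference of -0.027, and it cannot be told apart from an intact gene because values per exon were not analysed here.

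The higher E-box and D-box genes, of which 8 of 16 passed over all genes, are not accounted for by library scaling, since the lowest median of the E-box and D-box list over 4 scalings was 1.68. Nor do they rest on WT 1, without which the median was 1.64. Sampling of the groups at different times of day stays open. Of the E-box, D-box and ROR-element genes 21 of 21 had the sign of a single phase shift, 8 of them called. Loss of a clock repressor could move E-box genes in the same direction, and the labels give no time. These explanations cannot be told apart in this design, in which Cry1 itself was not lower.

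The Kupffer and antigen presentation lists had lower medians in the libraries labelled CRY1 KO, with 0 of 18 and 3 of 19 genes called and neither list called with an estimated correlation (adjusted p = 0.579 and adjusted p = 0.577 with an estimated correlation). An equal fall of all non-parenchymal cells is argued against, since endothelial markers lay 0.72 above Kupffer markers in median log2 difference (permutation p across genes 0.00011, 100000 resamples, genes not being independent) and 0.40 above without WT 1 (0.00053), while a smaller fall of stellate cells (median -0.13, and -0.33 without WT 2) beside Kupffer cells stays open. For antigen presentation WT 1 alone is argued against, since the median without it was -0.33. For Kupffer genes it stays open. Without WT 1 their median was -0.35, and the list was still lower by camera at the preset correlation (adjusted p = 0.0214). WT 3 lay at the level of the libraries labelled CRY1 KO. A difference between individual WT samples in macrophage content or inflammation may therefore account for the lower Kupffer median. A biological effect of genotype was not tested apart from these.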
